A study of Mus musculus with 6 samples.

How the data were processed

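Gene expression was measured on 6 arrays, 1 for each of 3 mouse lung adenocarcinoma-derived cell lines (KPR4, KPR5 and KPR8, on a mixed C57/B6-129SvJae background) under each of 2 treatments. Per the labels' protocols, cells grown in DME medium with 10% serum received 4-OH tamoxifen at 250 nM, dissolved in ethanol, 24 h before RNA was collected. The control culture of each line received ethanol. Per the labels, tamoxifen restores expression of p53 in these cells. Total RNA was extracted with Trizol, and 100 ng was amplified and biotin-labelled with the NuGEN Ovation V2 kit, per the labels.

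The deposited values are log2 expression per probe set, made by the authors with GCRMA 2.20.0 in R 2.11.0 per the submitters' processing notes. GCRMA subtracts a background modelled from probe sequence, normalizes between arrays and summarises the probes of a set. Whether it was run over these 6 arrays alone is not given in the sources used here. This step gives the arrays nearly the same distribution: their medians lay between 4.56 and 4.63 on the log2 scale. It would hide a change shared by most genes. The values came without detection calls. The 27 probe sets for Bacillus subtilis control transcripts lay between 1.13 and 2.84 and give the level of background on these arrays, and the highest value on any array was 14.34. Where a rise started from a vehicle array at or under the highest of these controls, that array was set to it and the rise is given as at least the resulting value. Scanner files were not used here, so saturation was not examined. No genome coordinates were used.

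The table holds 22690 probe sets, of which 64 are array controls. GEO's platform annotation gave 1 gene symbol for 20380 of the others and several for 691, and 1555 that are not controls have no symbol in the annotation used. Of the probe sets with 1 symbol, 20364 matched the GRCm38.p6 gene table by Entrez identifier, which changed 0 symbols. The named probe sets stand for 12393 genes. No gene was named from a probe set with several symbols. Probe sets were kept at log2 4 or above on at least 3 of the 6 arrays, and each gene was represented by its probe set with the highest mean over the 6 arrays, which left 7644 genes. The gene whose restored expression the labels describe, and 2 of the 9 genes named in advance, had no probe set named in the annotation used and are not reported here. The planned check of the labels on that gene was therefore not made.

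Changes with treatment were tested with limma 3.58.1 in R 4.3.3. The model had terms for cell line and treatment, variances were moderated with a trend on expression level, and p-values are 2-sided and Benjamini-Hochberg adjusted with a threshold of 0.05. The line term follows the stated design, in which each line received both treatments. As a check of the pairing, the deviations from the group means correlated, across genes, at 0.876 in KPR4, 0.737 in KPR5 and 0.761 in KPR8 between the vehicle and treated arrays of the same line, and below 0 for each pair of different lines. Centring on the mean of 3 lines pushes the latter below 0, so they add no separate support for the pairing. The residual degrees of freedom are 2 per gene, to which the moderation adds a prior of 12.9, so each p-value leans on the spread of other genes. The 3 lines are the replicates. Each p-value sets the mean response against a spread between them that is moderated towards that of other genes. With 1 array per line and treatment, no difference of response between lines could be tested. Errors of changes are standard errors from the limma fit and use the same moderated spread, so they are not a gene's own spread between lines. Errors of levels are standard deviations over 3 arrays.

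In simulated data with the same 7644 genes and design, 50 genes were changed at each of 4 sizes. The limma test recovered 30% of those changed by log2 0.5, 96% at 1, and 100% at 2 and at 3. False calls were 8, or 4.68% of the calls. The noise was drawn independently for each gene from variances fitted by limma, and each change was the same in every line. Real genes are correlated and respond unequally between lines, so these shares do not give the error rate of the real calls. The number of arrays limits the precision.

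Fixed lists of genes, 25 in number, were tested with limma's camera, which compares a list with the other genes, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks if the genes of a list move on balance in 1 direction, were alternatives. With an estimated correlation, camera relies on the 2 residual degrees of freedom, so small p-values are hard to reach. Differences between lines were tested by limma's moderated F-test in the same model. Sample groups, tests, lists, most alternative settings and the rule for named genes were set before the data were examined. The rule took the 10 largest rises and 10 largest falls among genes past the threshold with the same sign in each line. It added up to 4 members past the threshold from each list, or 2 from a list with none, then 9 genes named in advance, and the 5 genes with the largest F in each line that was the highest of the 3.

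The alternative settings set beforehand covered the line term, the filter, the choice of probe set, rescaling, the variance model, the threshold and leaving out each line. When a line was left out, a probe set had to reach the filter on 2 of the 4 remaining arrays. That rule replaced 3 of 4 after counts under the latter had been seen, because 3 of 4 removes genes that are off in vehicle. Camera was likewise given the variance trend after a first run without it. A run without probe sets of the _s_at and _x_at kinds, which can match several transcripts, one with the filter on 2 arrays, and one of a gut and liver list without a filter were added after the data were seen.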

Results

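The series profiled 3 mouse lung adenocarcinoma cell lines in which 4-OH tamoxifen restores p53, the tumour suppressor and transcription factor. Each line was measured once with ethanol vehicle and once with the drug at 250 nM for 24 h, giving 3 arrays per treatment. The share of probe sets at log2 4 or above was 57.2% to 57.6% on each array. The main question set by the design is which genes change when p53 is restored. The same arrays also show how far the 3 lines respond alike and how they differ from each other.

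Restoring p53 was accompanied by large rises of p53 target genes and smaller falls of genes of DNA replication and mitosis. The largest rise was that of Ak1, encoding adenylate kinase 1, from 3.74 ± 0.68 to 9.48 ± 0.49 on the log2 scale (SD, n = 3), a 53.3-fold difference. That vehicle mean is under the filter level of log2 4 and not far above background, so the fold is approximate. Cdkn1a, encoding the cyclin-dependent kinase inhibitor p21, went from 6.46 ± 1.11 to 11.09 ± 0.30, or 24.8-fold, with a log2 change of 3.17 on a dimmer probe set against 4.63 on this one. Dcxr, a carbonyl reductase, rose at least 21.4-fold, its vehicle level being above background on 2 of 3 arrays, and Dglucy rose 20.6-fold. The largest falls were those of Mcm5, a subunit of the replicative helicase, to a level 3.18-fold lower, and of Cdc6, which loads that helicase, to one 3.07-fold lower. In the limma fit the log2 change was 5.74 ± 0.17 (SE) for Ak1, with an adjusted p of 1.8e-11, and 4.63 ± 0.27 for Cdkn1a, with an adjusted p of 1.8e-08. It was -1.67 ± 0.19 for Mcm5 (adjusted p = 2.1e-05) and -1.62 ± 0.17 for Cdc6 (adjusted p = 1.5e-05).

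Of 7644 genes tested, 805 were higher and 683 lower with the drug in the limma fit, together 19.5%. Rises were larger than falls: 163 of the higher genes and 98 of the lower ones changed by log2 1 or more, and 37 and 0 by log2 2 or more. The direction was the same in each of the 3 lines for 797 of the 805 and for 680 of the 683. Among all tested genes it was so for 51.7%, where independent signs would give 25%. The test favours genes whose 3 changes agree, so the shares among called genes are largely set by the selection. The other largest rises were those of Trp53inp1 (4.09), Ephx1 (4.04), Ptp4a3 (3.58), Phlda3 (3.35), Psrc1 (3.20) and Sulf2 (at least 3.16), all as log2 changes. A dimmer probe set gave 2.27 for Trp53inp1. The other largest falls were Ncapg2 (-1.54), Bub1b (-1.49), Exo1 (-1.48), Pbk (-1.47), Cdca5 (-1.46), Pold2 (-1.46), Kif20a (-1.45) and Pole (-1.43). Dimmer probe sets gave -0.88 for Exo1 and -0.95 for Cdca5. These counts rest on comparing arrays within a line: without the line term, limma called 22 genes higher and 1 lower, and 67 of the 78 named genes past the threshold lost their call. Without KPR5, 526 genes were higher, and with 1 line left out 413 (no KPR8) to 444 (no KPR4) were lower, 438 without KPR5.

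**Figure D1:**
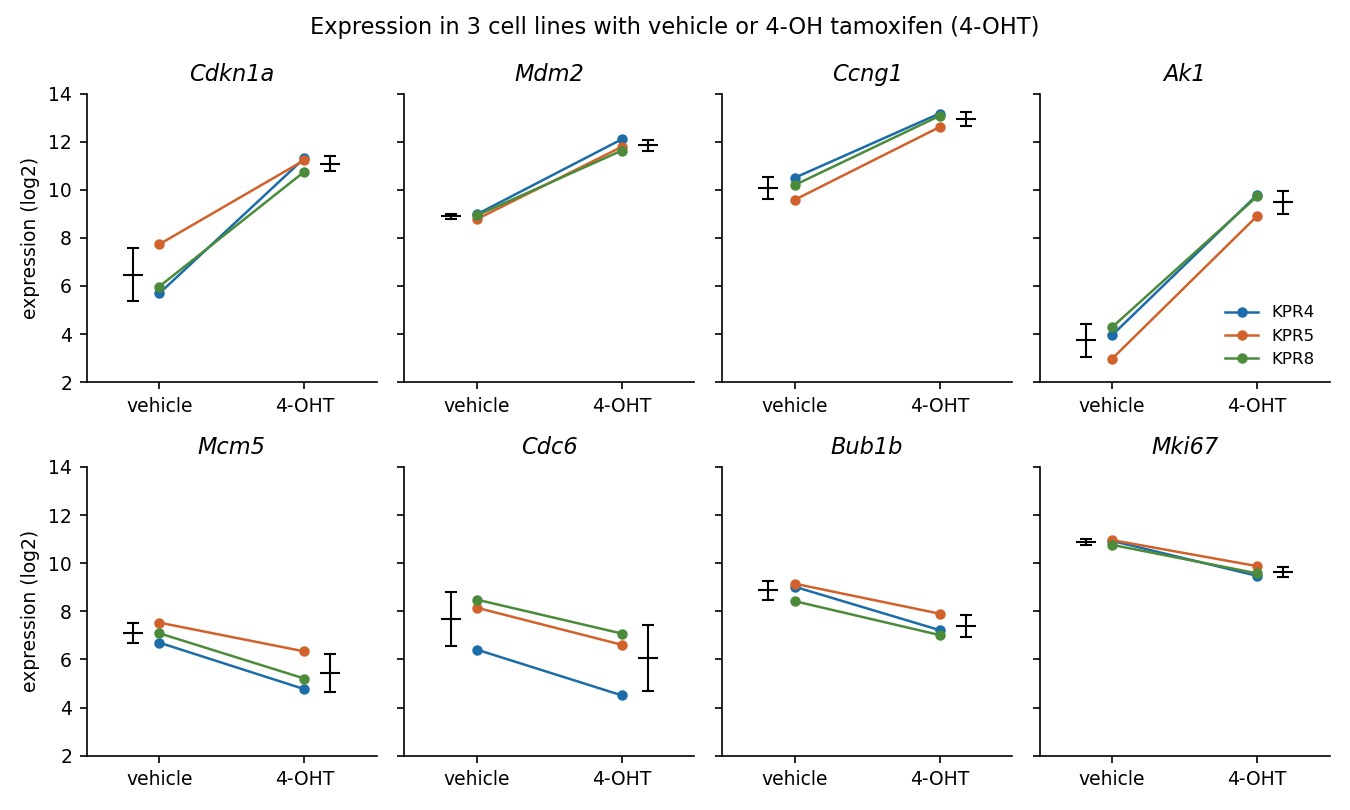
Expression on the log2 scale (vertical axis) of 8 genes with vehicle or 4-OH tamoxifen (horizontal axis), with 1 line joining the arrays of each cell line and black bars for the mean ± SD of 3 arrays. Cdkn1a, Mdm2, Ccng1 and Ak1 rose in KPR4, KPR5 and KPR8, and Mcm5, Cdc6, Bub1b and Mki67 fell in each.

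Among p53 targets of cell cycle arrest and feedback, 17 of 25 measured genes rose and 0 fell. Phlda3, an inhibitor of AKT signalling, rose by 3.35 ± 0.19 (SE). Mdm2, the ubiquitin ligase that degrades p53, rose by 2.94 ± 0.13 (adjusted p = 6.9e-10), and Ccng1, encoding cyclin G1, by 2.86 ± 0.11 (adjusted p = 1.9e-10). Psrc1 rose by 3.20 on its brightest probe set, but another of its probe sets gave -0.10. Dimmer probe sets gave a rise of up to 4.18 for Mdm2 and up to 4.41 for Ccng1. The median change of the list was 1.06 (limma's camera, adjusted p = 1.1e-15, against an adjusted p = 0.264 with an estimated correlation). Adjusted over the list alone, 18 rose.

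Of 11 measured p53 targets that act in cell death, 7 rose and 0 fell. Apaf1, the scaffold of the apoptosome, rose by 1.67 ± 0.16 and the nuclease gene Aen by 1.64 ± 0.17, or by as little as 0.96 on a dimmer probe set. Pmaip1, which encodes the BH3-only protein Noxa, rose by 1.62 ± 0.19 (adjusted p = 3.2e-05), and Ei24 by 1.30 ± 0.11. The list's median was 0.96 (camera, adjusted p = 2.1e-07, and adjusted p = 0.264 with an estimated correlation), and 7 rose adjusted over the list alone. Bbc3, encoding the BH3-only protein Puma, and Fas, a death receptor, were below the expression filter. The Bbc3 probe set lay between 2.86 and 3.43 on the 6 arrays. The Fas probe set read 3.03, 2.93 and 3.07 with vehicle and 5.64, 4.54 and 3.64 with the drug in KPR4, KPR5 and KPR8. In the limma fit without a filter its change was 1.60 ± 0.27 (adjusted p = 0.0023), and that of Bbc3 was 0.19 ± 0.11 (adjusted p = 0.347).

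The p53 targets of repair, redox balance and metabolism had 14 of 23 measured members higher, Ak1 and Dcxr among them, and 1 lower. Ephx1, a microsomal epoxide hydrolase, rose by 2.55 in KPR4, 4.90 in KPR5 and 4.67 in KPR8. Sulf2, a heparan sulfate sulfatase, rose by at least 4.73 in KPR4, where its vehicle level was at background, and by 2.83 and 1.92 in KPR5 and KPR8. Its vehicle mean over the 3 lines was 3.06, close to background, so the latter changes are approximate too. The member that fell was Polh, a translesion DNA polymerase (-1.10 ± 0.18, adjusted p = 0.00078), named after its values were seen. The median was 1.03 (camera, adjusted p = 5.3e-13, and adjusted p = 0.264 with an estimated correlation), and 15 rose and 1 fell adjusted over the list alone.

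Genes of G1/S and DNA replication fell together: 29 of 35 measured members were lower and 0 higher. Besides Mcm5 and Cdc6, Ung, a uracil glycosylase, fell by 1.42 on the log2 scale and Mcm10, a replication initiation factor, by 1.33. The median of the list was -0.92 (camera, adjusted p = 9.3e-21, and adjusted p = 0.268 with an estimated correlation), with 30 lower adjusted over the list alone. Of 47 measured genes of G2/M and mitosis, 43 fell and 2 rose. Bub1b, a spindle checkpoint kinase, changed by -1.49 ± 0.16, the kinesin Kif20a by -1.45 ± 0.16, Cdca3 by -1.38 ± 0.15 and the proliferation marker Mki67 by -1.24 ± 0.12 (adjusted p = 8.4e-06). The 2 that rose were Gtse1, which binds p53 and is itself induced by it, by 2.15 ± 0.23, and Ckap2, by 0.54 ± 0.16, the latter named after its values were seen. The list's median was -1.02 (camera, adjusted p = 7.0e-28, and adjusted p = 0.326 with an estimated correlation), and 44 fell and 2 rose adjusted over the list alone. Between treatments, the 3'-minus-5' signal of the Gapdh control probe sets, a measure of RNA integrity, moved by 0.24 in KPR4, 0.29 in KPR5 and -0.40 in KPR8, and that of Actb by 0.16, 0.39 and -0.07. The median change of the G2/M list in those lines was -1.25, -0.84 and -0.90.

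Ribosome biogenesis and MYC target genes were lower for 15 of 25 measured members and higher for 0. Srm, encoding spermidine synthase, changed by -0.92 ± 0.15, and the nucleolar protein genes Nolc1 and Nop58 by -0.80 ± 0.15 and -0.79 ± 0.13. The list's median was -0.42 (camera, adjusted p = 2.0e-08, and adjusted p = 0.326 with an estimated correlation), with 17 lower adjusted over the list alone.

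Lysosome and autophagy genes rose for 10 of 24 measured members, with 0 lower. Atp6v0d1, a subunit of the vacuolar proton pump, rose by 1.47 ± 0.18, and Tpp1 and Ctsd, which encode lysosomal proteases, by 1.46 ± 0.16 and 1.30 ± 0.15. The median was 0.29 (camera, adjusted p = 7.6e-05, and adjusted p = 0.507 with an estimated correlation), with 10 higher adjusted over the list alone; fry gave an adjusted p of 0.0869. Secreted inflammatory and senescence-associated factors rose for 8 of 17, with 0 lower. The matrix protease gene Mmp10 rose by 1.31 ± 0.19 and the cytokine genes Csf2 and Csf1 by 1.06 ± 0.18 and 0.79 ± 0.20, although without KPR4 the change of Csf1 was 0.55 (adjusted p = 0.130), and without KPR5 0.74 (adjusted p = 0.0561). The median was 0.42 (camera, adjusted p = 0.0031, and adjusted p = 0.326 with an estimated correlation), with 9 higher adjusted over the list alone.

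NRF2 and glutathione genes rose for 5 of 19 measured members and fell for 0. Hmox1, encoding haem oxygenase 1, rose by 1.71 ± 0.18, Gclc, the catalytic subunit for glutathione synthesis, by 1.36 ± 0.20, and catalase, Cat, by 0.86 ± 0.12. The median was 0.23 (camera, adjusted p = 0.0059, and adjusted p = 0.713 with an estimated correlation), and 6 rose adjusted over the list alone. Over the alternatives its adjusted p ran from 0.00026 to 0.713, and the call ended without the line term (adjusted p = 0.0534), without KPR4 (adjusted p = 0.0777) and with fry (adjusted p = 0.167). Of 17 measured TGF-beta and YAP targets, 6 rose and 0 fell, among them Ltbp2 (1.21 ± 0.19) and Ccn1 (0.89 ± 0.14), both matrix proteins. The median was 0.26 (camera, adjusted p = 0.012, and adjusted p = 0.326 with an estimated correlation), with 7 higher adjusted over the list alone. Its adjusted p ran from 0.0027 to 0.326 over the alternatives, and the call ended without KPR4 (adjusted p = 0.0511) and with the mean of a gene's probe sets (adjusted p = 0.0601). Lats2 of the same list rose by 0.74, but another of its probe sets gave -0.23.

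Estrogen receptor targets were included because 4-OH tamoxifen binds that receptor. Of 16 fixed genes 5 passed the filter, and 4 rose and 0 fell, also adjusted over the list alone: Ctsd (1.30), Nrip1 (0.65), Xbp1 (0.54) and Igfbp4 (0.42). Ctsd, Xbp1 and Igfbp4 are members of other lists too. Other probe sets gave -0.20 for Nrip1, -0.41 for Igfbp4 and 0.15 for Xbp1. The calls of Nrip1, Xbp1 and Igfbp4 ended without KPR4, with adjusted p = 0.0855, 0.147 and 0.0682, and those of Xbp1 and Igfbp4 also without KPR5 (adjusted p = 0.225 and 0.0992). The fifth gene, Tff1, had a change of 0.12 ± 0.17. The median was 0.54 (camera, adjusted p = 0.0033, and adjusted p = 0.507 with an estimated correlation), and the call ended without the filter (adjusted p = 0.662), with the mean of probe sets (adjusted p = 0.0838) and with fry (adjusted p = 0.0869). The receptor genes were near background, with Esr1 between 2.87 and 3.37 and Esr2 between 2.75 and 3.36. Thus 11 of the 25 lists passed with the preset correlation and 0 with an estimated one. The count of 0 does not show that correlation between genes accounts for the shifts. For the arrest list the estimated correlation, -0.0075, was below the preset 0.01, yet camera's unadjusted p went from 1.3e-16 to 0.012. With 2 residual degrees of freedom that variant can hardly reach a small p. For lists with a higher estimate, such as G2/M (0.43), the 2 effects cannot be told apart.

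**Figure D2:**
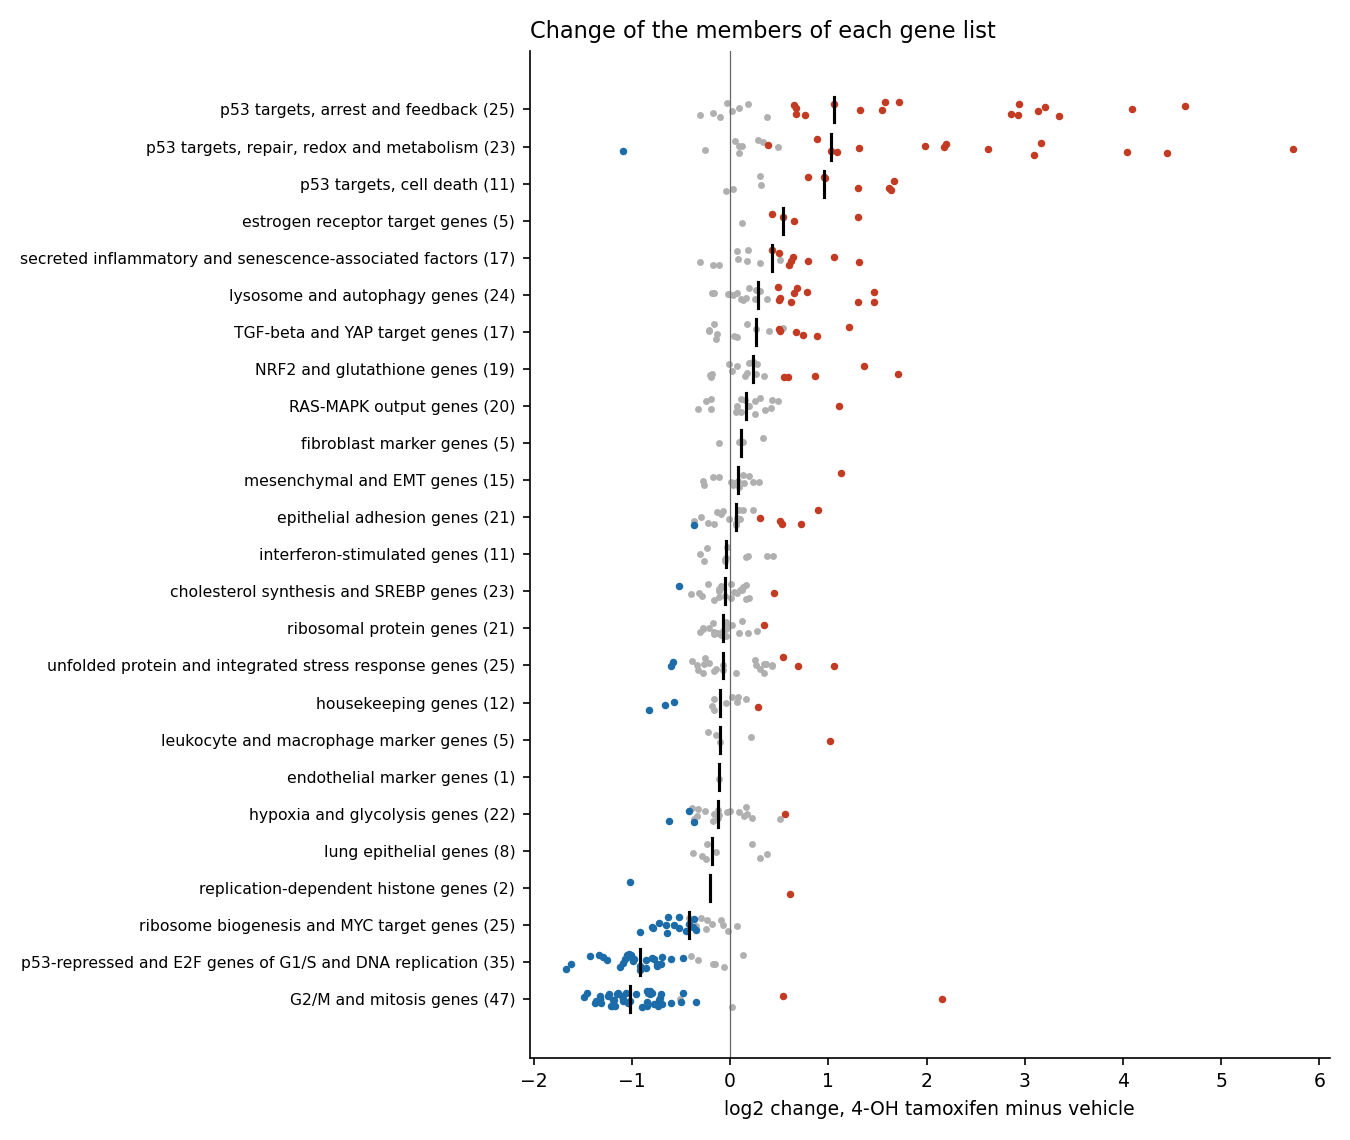
Log2 change with 4-OH tamoxifen minus vehicle (horizontal axis) of each measured member of the 25 gene lists (vertical axis, with the number of members in parentheses). Red points rose, blue points fell and grey points did not pass the limma threshold, and black bars mark medians, which run from -1.02 for G2/M and mitosis genes to 1.06 for p53 targets of arrest and feedback.

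The remaining lists did not pass in camera. Of 20 RAS-MAPK output genes 1 rose, the EGF receptor ligand gene Ereg (1.11 ± 0.15), and the list's adjusted p was 0.107. Over the alternatives its adjusted p ran from 0.0275 to 0.776: it was 0.0275 without KPR5 and 0.0415 without KPR8, 0.0478 without a filter and 0.0394 with a stricter one. Of 21 epithelial adhesion genes 5 rose and 1 fell (adjusted p = 0.666), with Cldn4, a tight junction protein, higher by 0.89 ± 0.18. In fry this list had an adjusted p of 0.0449. Of 15 mesenchymal genes 1 rose, the matrix protein gene Tnc (1.13 ± 0.16), and 0 fell (adjusted p = 0.566). Lung epithelial genes had 0 of 8 members past the threshold (adjusted p = 0.706), with values of -0.38 ± 0.17 for Aqp5 and 0.37 ± 0.17 for Abca3. Without KPR5, Aqp5 passed the threshold (-0.64, adjusted p = 0.0427). Probe sets for Nkx2-1, the lung lineage transcription factor, lay between 2.40 and 2.83, and those for Sftpc, surfactant protein C, did not exceed 3.13.

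Of 23 cholesterol synthesis genes 1 rose and 1 fell (adjusted p = 0.706). Of 25 genes of the unfolded protein and integrated stress responses 3 rose and 2 fell (adjusted p = 0.706), with Sesn2, also a p53 target, higher by 1.06 ± 0.15 and Phgdh, of serine synthesis, lower (-0.58 ± 0.11, although -0.35 with an adjusted p of 0.255 on another probe set). Of 22 hypoxia and glycolysis genes 1 rose and 3 fell (adjusted p = 0.255). Interferon-stimulated genes had 0 of 11 past the threshold (adjusted p = 0.902). Of 19 fixed replication-dependent histone genes only 2 were measured, too few to speak for the list. Both changed: H2ax by -1.02 ± 0.16 and H1f2 by 0.61 ± 0.14 (adjusted p = 0.740 for the list). The call of H1f2 ended without KPR4 (adjusted p = 0.0587), and another of its probe sets was at 0.03. Ribosomal protein genes had 1 of 21 higher and a median of -0.07 (adjusted p = 0.307). The member was Rps9 (0.34), which had -0.23 on another probe set and lost its call without KPR4 (adjusted p = 0.0749) or KPR8 (adjusted p = 0.0561). Of 12 housekeeping genes 1 rose and 3 fell, with a median of -0.11 (adjusted p = 0.253), and Tubb5, a tubulin, was the furthest from 0 (-0.82 ± 0.13). Among markers of other cell types, 0 of 5 fibroblast genes and 0 of 1 endothelial gene passed, and 1 of 5 leukocyte genes did, Cd68 (1.02 ± 0.15), a lysosomal protein of macrophages (adjusted p = 0.649, 0.740 and 0.706 for the lists). For the interferon, stress response and leukocyte lists the median was below 0 while camera's direction was up.

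The change with the drug was similar across the 3 lines. Across 7644 genes, which are not independent replicates, the log2 changes correlated with Pearson's r of 0.727 between KPR4 and KPR5, 0.656 between KPR4 and KPR8 and 0.623 between KPR5 and KPR8. Spearman's rho was 0.608, 0.527 and 0.487. Genes called with limma in 2 lines, and also among the 7644 past the filter over all 6 arrays, were then looked up in the line left out. That filter uses the left-out line too, so the choice of genes was not fully separate from it. For KPR4, 97.2% of 536 higher genes and 97.0% of 440 lower genes had the same direction there. For KPR5 the shares were 96.7% of 520 and 96.5% of 433, and for KPR8 89.7% of 591 and 93.9% of 410. Of all genes, 45.9% to 54.1% had the direction in question. Changes of log2 1 or more were seen upward in 216 genes and downward in 146 in KPR4, in 281 and 105 in KPR5, and in 173 and 163 in KPR8. Cdkn1a rose by 5.62, 3.50 and 4.78 in KPR4, KPR5 and KPR8, and Trp53inp1, an autophagy and stress protein gene, by 3.03, 4.81 and 4.43. For Cdkn1a and Trp53inp1 the vehicle levels varied more between lines (SD 1.11 for each) than the treated levels (SD 0.30 and 0.22). Whether such differences of the change between lines exceed the error could not be tested with 1 array each.

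**Figure D3:**
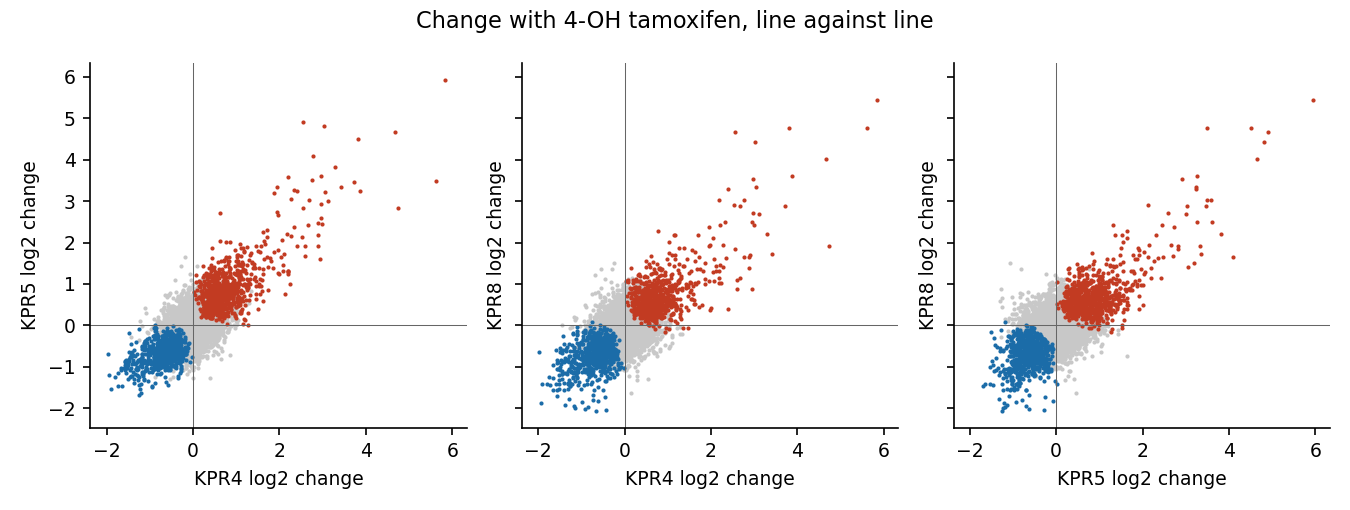
Log2 change with 4-OH tamoxifen minus vehicle in one cell line (horizontal axis) against another (vertical axis) for 7644 genes, with the 805 higher genes in red, the 683 lower genes in blue and others in grey. Pearson's r across genes is 0.727, 0.656 and 0.623 from left to right.

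The 3 lines differed from each other in more genes than treatment changed. In limma's F-test 3210 genes, 42.0%, differed between lines, and 867 of them also changed with treatment. The range between lines was log2 1 or more for 1072 genes and 3 or more for 73. KPR4 stood furthest apart: 26 genes were at least log2 3 above both other lines in KPR4, against 2 in KPR5 and 1 in KPR8, and 2, 0 and 5 were as far below. Without KPR4, 1560 genes differed between the other lines.

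In KPR4, Selenop, encoding a plasma selenium carrier, averaged 11.67 over both arrays, against 4.64 in KPR5 and 4.76 in KPR8 (adjusted p = 5.7e-12). Hnf4a, a transcription factor of liver and gut epithelium, averaged 12.45, 7.64 and 5.63, and Tff1, a gastric mucosal peptide, 9.81, 4.29 and 3.52. Other Hnf4a probe sets did not pass the filter. One read 8.67 and 9.55 in KPR4 and 2.56 to 3.56 in the other lines. Another read 5.09 and 4.38 in KPR4 and 1.52 to 2.175 in the others, and a further one lay between 3.07 and 3.395 on all arrays. Gsta4 and Aldh3a1, enzymes that clear reactive aldehydes, were 3.43 and 5.95 above the next line. In KPR5, Crip1 was 3.22 and Cldn6, a claudin, 1.54 above the next line. Tm4sf1, Ctse and Bcl2l15 were 0.35, 0.14 and 0.95 above the next, so that Tm4sf1 was high in KPR5 and KPR8 and low in KPR4, and Ctse, a gastric protease, was high in KPR4 and KPR5. In KPR8, Prl, encoding prolactin, averaged 11.40, against 4.01 in KPR4 and 5.10 in KPR5, and Glrp1 was 2.43 and the platelet chemokine gene Ppbp 1.13 above the next line. Ctla2b and Bmp7 were 0.04 and 0.55 above KPR5. The F-test's calls for Tm4sf1, Ctla2b and Bmp7 ended without KPR4 (adjusted p = 0.164, 0.906 and 0.0876), and that for Ctse without KPR8 (adjusted p = 0.487).

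**Figure D4:**
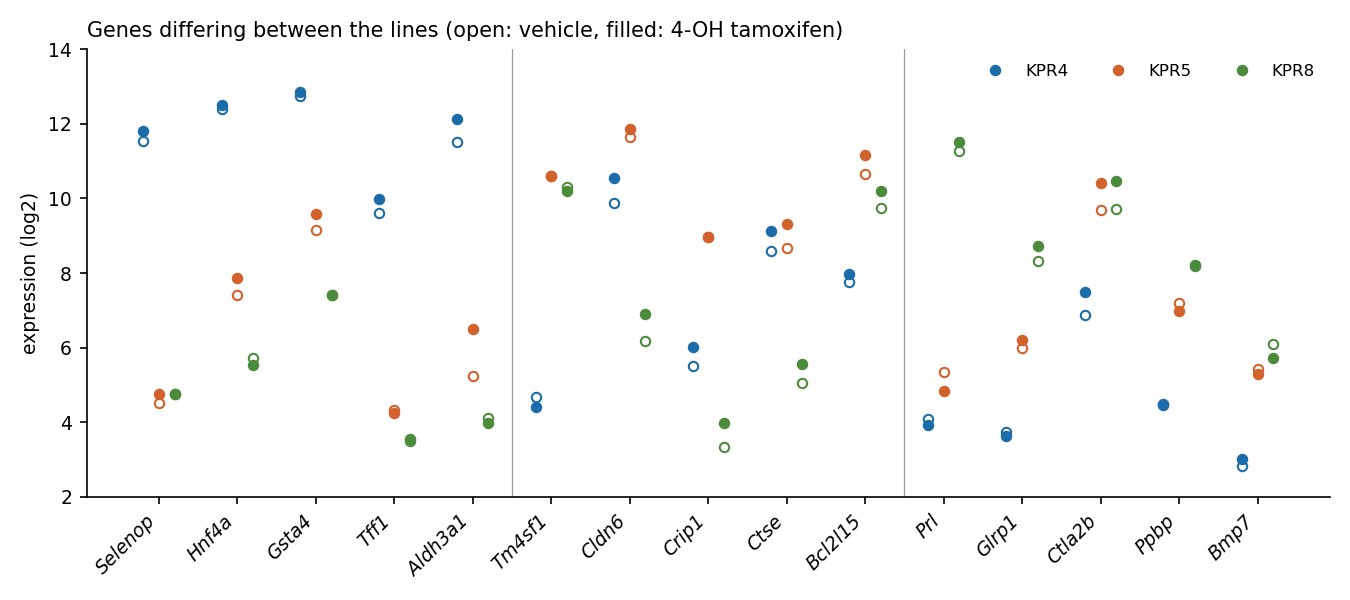
Expression on the log2 scale (vertical axis) of the 15 genes with the largest F in each line (horizontal axis; KPR4, KPR5 and KPR8 genes from left to right), with open circles for vehicle and filled circles for 4-OH tamoxifen. The KPR4 genes lie at least 3.43 above the next line on average, whereas Ctse and Ctla2b differ from the next line by 0.14 and 0.04.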

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

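The tests of the fall of cell cycle genes below were chosen after that result was seen. The other splits of the arrays were planned beforehand.

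Probe sets without a single gene name were outside the comparisons above. They number 2246, and of the 1156 past the filter 71 were higher and 115 lower with the drug in limma.

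Bcl2l1, which encodes the survival protein Bcl-xL, moved in opposite directions: its log2 change was 1.51 in KPR8 and -1.07 in KPR5, with -0.24 in KPR4. The difference between lines was not tested, since each line has 1 array per treatment, and over the 3 lines its limma adjusted p was 0.919. The pattern depends on the probe set: another gave 1.65 in KPR8, -0.61 in KPR5 and 0.23 in KPR4, and a further one 0.49, 0.56 and 0.67, a rise of 0.57 over the 3 lines with an adjusted p of 0.0288 when each probe set was tested in limma.

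The real grouping gave 805 higher and 683 lower genes, and the other splits of the 6 arrays into 3 and 3 gave at most 0. In each direction 1 of the 10 splits, the real one, reached its count. The splits that like the real one part each line, and those that do not, all called 0. With 10 splits the share cannot go under 0.1, which is too few for a share under 0.05.

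The G2/M and replication lists fell in each line. A normalization fault may lower any set of genes, but the lowest median among ribosomal protein, housekeeping and spike control probe sets was -0.11, far from the -1.02 and -0.92 of these lists, which argues against it as the whole cause. Line by line the control medians reached -0.25 (ribosomal protein genes), -0.20 (housekeeping genes) and -0.21 (spike controls) in KPR8, where the lists had -0.90 and -0.96, and the spike controls had 0.25 in KPR4. Loss of RNA integrity is argued against as the whole cause too: the 3'-minus-5' difference rose in KPR4 and KPR5 for Gapdh and Actb, but in KPR8 it fell for Gapdh (-0.40) and hardly moved for Actb (-0.07), and the weakest median of either list in any line was still -0.70. An effect of 4-OH tamoxifen or of the recombinase it activates, without p53, stays open, since 0 arrays come from treated cells whose p53 cannot be restored, and so does the restoration of p53 that the labels name, as a hypothesis.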

How the results depend on the processing

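The run without _s_at and _x_at probe sets and the filter on 2 arrays were chosen after seeing the data. The cause of a change was not tested unless stated. Counts stayed within 1.5 times the limma counts under the filters, probe set choices, rescaling, variance models and the 0.10 threshold: 674 to 1139 higher, 565 to 953 lower. Signal over background limits what can be seen of genes near log2 4, and robust variance was not run for the lists.

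Without the replicate block by cell line, 22 genes were higher and 1 lower, each among those of the blocked fit, and NRF2 genes had an adjusted p of 0.0534; no other list call changed. With log2 1 required, 163, 98 and 1072 genes (between lines) and 3 lists stayed. The 8 lists lost by that rule, their medians being smaller, were cell death (2.1e-07), replication (9.3e-21), secreted factors (0.0031), TGF-beta (0.012), estrogen receptor (0.0033), NRF2 (0.0059), lysosome (7.6e-05) and ribosome biogenesis (2.0e-08).

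Without a filter, RAS-MAPK passed (0.0478), estrogen receptor did not (0.662), lung turned (0.796), and the mean correlation between lines was 0.610. With the stricter filter RAS-MAPK passed (0.0394), and histones (0.203), interferon (0.886) and stress response (0.861) turned. With the mean of probe sets TGF-beta (0.0601) and estrogen receptor (0.0838) lost their call and Rps9 turned (-0.0136). Single probe sets turned Psrc1 (-0.10), Lats2 (-0.23), Nrip1 (-0.20), Igfbp4 (-0.41), Idi1 (-0.0839), Rps9 (-0.23) and Ywhaz (-0.37). Without _s_at and _x_at probe sets RAS-MAPK passed (0.0445) and Rps9 turned (-0.23).

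With camera's estimated correlation 0 lists passed: p53 lists 0.264 each, replication 0.268, G2/M, secreted factors, TGF-beta and ribosome biogenesis 0.326, estrogen receptor and lysosome 0.507, NRF2 0.713. That variant has little power at 2 residual degrees of freedom. With fry, epithelial adhesion passed (0.0449) and estrogen receptor (0.0869), NRF2 (0.167) and lysosome (0.0869) did not.

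Leaving out each cell line (replicate) in turn gave 526 to 600 higher, 413 to 444 lower and 1560 to 2562 genes between lines, with fewer samples in each fit. The adjusted p of lists then ran from 0.0275 to 0.712 for RAS-MAPK, 0.0027 to 0.0511 for TGF-beta, 0.0986 to 0.764 for cholesterol, 0.337 to 0.932 for interferon, 0.388 to 0.932 for the stress response and 0.00026 to 0.0777 for NRF2 genes. The log2 change of Idi1 ran from -0.165 to 0.512. Alternatives for the restored gene were not run.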

Other observations

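Gene families were grouped by symbol after the values were seen, so their limma camera tests describe the pattern and are not independent evidence for it. Some families share members with the fixed lists: Cenpa, Cenpe and Cenpf with the G2/M list, and Atp6v0d1 and Atp6v1h with the lysosome list. Augmin subunits (Haus genes), which nucleate microtubules within the spindle, fell for 7 of 8 measured members with 0 higher, a median of -0.77 and an adjusted p of 0.00013. Cenp genes, of the centromere and kinetochore, fell for 9 of 12, with a median of -0.78, and 1, Cenpt, rose (0.85 ± 0.17). Condensin and SMC genes fell for 7 of 11 (median -0.66), and nucleoporins for 9 of 16 (median -0.50), Nup107 by 1.09 on the log2 scale. RNA exosome genes were lower for 3 of 8 (median -0.38) and importins and exportins for 5 of 18 (median -0.24). Vacuolar ATPase subunits rose for 8 of 15 with 0 lower and a median of 0.39, near 0.44, 0.48 and 0.40 in KPR4, KPR5 and KPR8. With an estimated correlation none of these families passed: the adjusted p lay between 0.116 for several and 0.171 for the RNA exosome. Septins (1 of 7 lower, adjusted p = 0.618) and tetraspanins (2 of 12 higher, adjusted p = 0.477) did not pass with the preset correlation either.

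Several single genes were picked out after their values were seen. Rb1, encoding the retinoblastoma protein, rose by 1.94 ± 0.17 (limma, adjusted p = 2.8e-06), in KPR4, KPR5 and KPR8 by 2.04, 1.65 and 2.12. The transcription factor gene Foxo3 rose by 1.55 ± 0.14 and the receptor genes Notch3 and Notch1 by 1.67 ± 0.16 and 1.08 ± 0.20. Another Notch1 probe set gave 0.60, and another of Notch3 was at background on 2 of 3 vehicle arrays and gives no exact change. Egfr rose by 1.03 ± 0.18, with 1.47, 0.64 and 0.98 in the 3 lines. Cdkn2a, from whose locus an activator of p53 is made, read 7.26 to 8.52 on the 6 arrays, and its change was -0.18 ± 0.16 (adjusted p = 0.482).

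The tests of liver-cell contamination, of lung gene loss and of the gut and liver list without a filter were chosen after related values were seen. KPR4 expressed Hnf4a, Tff1 and the intestinal transcription factor gene Cdx2 (9.94, against 5.24 in KPR5 and 6.80 in KPR8) above the other lines, although another Cdx2 probe set read 4.35 and 3.60 in KPR4 and 3.41 to 3.81 in the others. A gut and liver lineage programme in KPR4 is a candidate explanation: of 55 other gut and liver genes, listed after those 3 were noticed but before values of the 55 were seen, 18 were measured, and their median difference from the other lines, 0.62, was at the 99.99th percentile of 10000 random lists matched on level, with 9 higher, such as Lgals4 (8.90) and Cdh17 (3.50), and 2 lower, Krt20 (-0.74) and Afp (-2.27). The filter asked for 2 arrays, so a gene could enter on the KPR4 arrays alone, and 6 of the 18 averaged log2 4 or more in KPR4 only; without a filter the 46 genes on the array were at percentile 100, with 13 higher and 3 lower, but their median was 0.18, under the 0.5 asked for, so the programme stays open. Contaminating liver cells also stay open: under a bound written once the Alb level was known they were to be excluded if Alb, Apoa1, Fga, Fgb and Serpina1a all stayed under log2 4 on the KPR4 arrays; Serpina1a had no probe set named in the annotation used, and Alb (3.44), Fga (3.32) and Fgb (2.89) did but Apoa1 reached 4.99. As a set, the 10 measured genes of the lung list were not lower in KPR4 than in the other lines. Their median was -0.07, at the 40.1th percentile. In KPR4, 4 were higher: Abca3 (1.03), Foxa2 (1.80), Cebpa (2.78) and Muc1 (1.68). The 1 lower, Aqp5, was lower still in KPR8 (7.57, against 7.83 in KPR4 and 10.04 in KPR5). Lung genes near background in each line, such as Nkx2-1 and Sftpc, cannot show a loss. Cebpa averaged 6.27 in KPR4 but 3.65 in KPR5 and 3.34 in KPR8, under the filter level, so it entered on the KPR4 arrays. Loss of lung genes in KPR4 alone therefore stays open. Contamination with gut cells was not tested.

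Mdm2 and Ccng1 changed less on their brightest probe set than on dimmer ones, and compression of high intensities might cause this. Of the named genes Ccn1 (0.89 against 1.21), Tpp1 (1.46 against 1.81) and Sesn2 (1.06 against 1.29) also changed less on theirs, and Cdkn1a (4.63 against 3.17), Trp53inp1 (4.09 against 2.27) and Aen (1.64 against 0.96 at the least) changed more. Of these 6, the brightest probe set averaged log2 10 or more for Ccn1 alone. Named genes that fell also went both ways. Nolc1 (-0.80 against -0.92) and Mcm10 (-1.33 against -1.415) changed less on theirs. Exo1 (-1.48 against -0.88), Cdca5 (-1.46 against -0.95) and Tubb5 (-0.82 against -0.60) changed more, and Tfrc (-0.57) lay between its others (-0.685 and -0.45). Tubb5 and Tfrc were above log2 10 with both treatments. Over 746 genes with a called probe set, the brighter of a pair changed by 0.07 more than the dimmer (median), with a difference of 0.19 where the brighter averaged under log2 8 (228 genes), 0.11 from 8 to 10 (270 genes) and -0.0542 at 10 or more (248 genes, quartiles -0.33 and 0.18), and with a smaller change on the brighter probe set for 32.5%, 40.0% and 56.0% of these genes. Before this was computed, a median at 10 or more under -0.2 was to speak for compression and one between -0.1 and 0.1 against it; the median lies in the latter range, but that bound was too weak to exclude compression, since it left out the spread, whose quartiles reach past -0.2, so compression stays open; the 2 genes at 10 or more whose dimmer probe set changed by log2 2 or more (median -1.39) are Mdm2 and Ccng1 themselves and only restate what prompted the test. Cross-hybridising probe sets stay open as well, since over all genes the brighter did not change less, and without them the median was 0.11.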
